A study of Danio rerio with 32 samples.

How the data were processed

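RNA sequencing values were analysed for 32 libraries from eyes and brains of zebrafish embryos, 4 libraries in each of 8 groups defined by tissue, photoperiod and treatment. The deposited table gives FPKM (fragments per kilobase, scaled for library size) for 32520 genes in each library, as the authors computed it, with a gene length, position and type for each gene. Libraries were read as paired ends on a NovaSeq X Plus after random-hexamer priming, and the labels describe both directional and non-directional preparation without saying which was used, so values of overlapping, antisense and closely related genes are uncertain. The submitters' processing notes name HISAT2 2.0.5 and featureCounts 1.5.0-p3 without their roles, and the genome build and annotation release are not given in the sources used here. The table's 2 columns of pooled group means were not used here.

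The unit was tested on the values. In each library FPKM times gene length was a whole multiple of 1 step within a tolerance of 0.05 for 100% of values, which gave whole fragments per gene and the total per library. The totals ran from 8.83 to 16.13 M (mega) fragments. The divisor behind the FPKM values was 0.899 to 1.16 times the recovered total, so the divisor was not the plain column total. Replicate pairs spread more than counting alone allows, taken over the genes together. The chi-square per degree of freedom ran from 6.36 to 230.39. It was at most 76.91 without the library labelled brain DD PFNA replicate 3 and 43.38 without eye DD PFNA replicate 4 as well. The part of counting error in genes with few fragments was not tested apart.

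Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend in the mean) on log2(FPKM + 1), so that every fold change is on that scale and is smaller than the ratio of FPKM for genes near 1 FPKM. The 16 libraries of a tissue were fitted together with 1 mean per group, for genes of at least 1 FPKM in at least 4 of the 16 libraries (18204 genes in eyes, 17437 in brains). Within each tissue the contrasts were PFNA against DMSO under LD and under DD, DD against LD with DMSO and with PFNA, and the difference of the PFNA effect between DD and LD. The difference of the PFNA effect between eye and brain used all 32 libraries and 16441 genes. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast and called under 0.05.

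Gene lists (40 lists, 1184 entries, of which 1150 matched a gene of the table) were written before the data were examined, as were the tests, the filter, the other settings to be tried and the rule for naming genes. List members were counted as rising or falling after adjustment over all genes, and again adjusted over the list alone. Each list with at least 5 tested members was compared with the other genes by limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. Of 395 pairs of a list and a contrast within a tissue, camera called 152, of which 20 held with an estimated correlation, and the median, mean and test did not differ in sign for any called pair.

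The rule names, for each contrast, the 6 largest rises and 6 largest falls among called genes with a name and a higher group mean of at least 1 FPKM. To these it adds the 3 called members with the smallest p of each list, at most 24 in all, and a fixed set of clock genes for photoperiod and of lipid, stress and cell type genes for PFNA. The text names fewer of these, in their order, and says where a gene was chosen after its values were seen. Some results that the rule would name are not reported here.

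The tests were tried on simulated data made from the values. Of 100 genes changed 2-fold, limma called 76 in LD eyes, 44 in DD brains, 41 for the interaction in eyes and 44 for the tissue difference under LD, and of 100 genes changed 4-fold it called 97, 86, 89 and 93, with 3 to 6 false calls among the unchanged genes. The changed genes were drawn from genes well above the filter of 1 FPKM, so recovery near the filter was not tried. The spread was drawn for each gene alone, without the spread that genes of a library share. In brains it included that of the library labelled brain DD PFNA replicate 3.

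Other settings planned in advance were a pseudocount of 0.1, no filter, median-ratio scaling, quantile normalization, the replicate number as a block, limma's array weights, a fit of only the 2 groups compared, leaving out each library in turn and camera with an estimated correlation. Added after seeing the data were limma with voom weights on the recovered fragments and, for contrasts and genes in which they take no part and for the gene lists, the fits without the library labelled brain DD PFNA replicate 3 or eye DD PFNA replicate 4. The fit of the tissue difference under DD without both was also added then. With voom the counts were 2169, 1981, 2733, 3100 and 25 for the eye contrasts in the order above, 409, 669, 1018, 1260 and 0 for the brain contrasts, and 1 and 11 for the tissue differences under LD and DD. No library was left out of the planned tests.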

Results

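RNA was sequenced from eyes and brains dissected from wild-type zebrafish embryos that were kept from 0.75 to 120 hours post fertilization (hpf) in 0.1% DMSO with 0 or 12.5 µM PFNA (perfluorononanoic acid, a long-chain perfluoroalkyl acid). The embryos were raised under 14 h of light and 10 h of dark per day (LD) or under 24 h of dark (DD). Crossing tissue, photoperiod and treatment gave 8 groups of 4 libraries each, 32 libraries in all. The series title, treatment protocol and sample labels name PFNA, while the series' design text names PFHxS at the same dose, and the sample labels are followed here. The recovered fragment totals ranged from 8.83 to 16.13 M (mega) per library with a median of 11.44 M. Thus 1 FPKM in a transcript of 1 kilobase stood for 8.45 to 17.0 fragments. Between 15446 and 17116 genes reached 1 FPKM in a library, and mitochondrially encoded transcripts took 4.66% to 10.01% of the fragments. Nothing in the labels states that replicates came from separate clutches, so the p-values measure the spread between these samples.

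A pair of libraries stood apart from the rest. The library labelled brain DD PFNA replicate 3 held 1282.91 FPKM of the rod opsin rho, against 0.13 to 7.74 FPKM in the other 15 brain libraries and 1160.79 to 3592.55 FPKM in 15 eye libraries. The same library held 832.55 FPKM of the lens crystallin crygm2d1 (0 to 2 FPKM in the other brain libraries) and 3.77 FPKM of the myelin gene mbpa (46.65 to 100.93 FPKM). On a scale drawn from 773 eye-enriched and 466 brain-enriched genes in the LD DMSO groups, with those brains at 0 and those eyes at 1, it lay at 0.972, and the other 11 brain libraries outside the groups that set the scale lay between 0.00182 and 0.0408. The library eye DD PFNA replicate 4 lay with the eyes but had the largest mitochondrial share, 10.01% of fragments, and 8022.33 FPKM of the mitochondrial oxidase gene mt-co1 against 3233.84 to 4822.95 FPKM in the other eye libraries. Both libraries stayed in the tests as planned, and the counts within a tissue are also given without the one of that tissue. For the gene lists, and where the library takes no part in the contrast, that alternative was added after the data were seen.

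**Figure D1:**
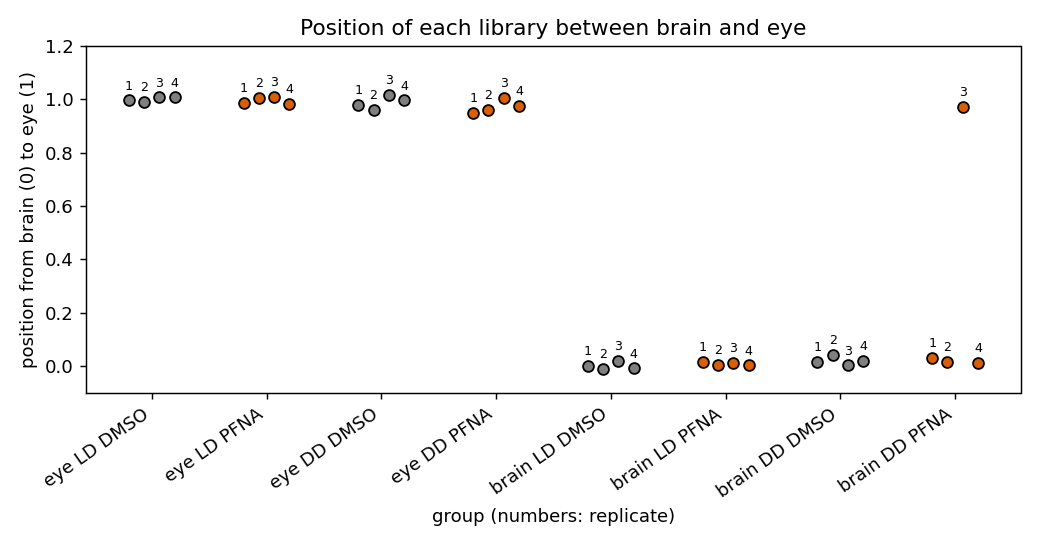
Position of each of the 32 libraries between brain (0) and eye (1), from genes that differed between the LD DMSO eyes and brains. The library labelled brain DD PFNA replicate 3 lies at 0.972, and the other brain libraries outside the groups that set the scale lie between 0.00182 and 0.0408.

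Changes below are log2 fold changes on the log2(FPKM + 1) scale from limma with 4 libraries per group, given with their standard errors, and p-values are adjusted over all genes tested. Genome positions are those of the deposited gene annotation, whose build is not named. The first comparison asks what PFNA changed in eyes kept under LD. The AP-1 transcription factor gene fosl1a (ENSDARG00000015355, chromosome 14, 30739476 to 30747686, minus strand) averaged 22.9 ± 8.08 FPKM (SD, n = 4) with PFNA and 1.18 ± 0.636 FPKM (SD, n = 4) with DMSO, a change of 3.44 ± 0.24 (adjusted p = 3.94e-07). The cytokine gene il11a rose by 3.17 ± 0.25, the transcription factor gene cebpb by 3.07 ± 0.17, the matrix metalloproteinase gene mmp9 by 3.003 ± 0.324 and the prostaglandin synthase gene ptgs2b by 2.88 ± 0.20. The largest falls among protein-coding genes were in xkr8.2 (-1.77 ± 0.23), in the collagen chaperone gene serpinh1b (-1.495 ± 0.181) and in the histone gene hist1h2a3 (-1.32 ± 0.23). In all, 1956 of 18204 genes passed, 1283 higher and 673 lower with PFNA, and 423 of them differed over 2-fold.

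Genes that light induces in zebrafish cells rose in LD eyes with PFNA: 9 of 10 measured members rose, 1 did not pass and 10 rose adjusted over the list alone. They included the photolyase-related gene cry-dash (1.94 ± 0.12, from 9.98 ± 0.958 to 41.3 ± 5.06 FPKM, SD, n = 4), the DNA repair gene xpc and the period gene per2 (1.74 ± 0.20, from 65.5 ± 12.8 to 219 ± 28.6 FPKM, SD, n = 4). Camera gave this list an adjusted p = 5.14e-12, and 0.00102 with an estimated correlation. Of 21 inflammation genes 13 rose and none fell (14 adjusted over the list alone), among them the cytokine signalling genes stat3 (1.54 ± 0.16) and il6st. The inflammation list had an adjusted p = 0.0184 with an estimated correlation. Of 28 immediate early genes 17 rose and 1 fell (21 and 1 adjusted over the list alone). This call had an adjusted p = 0.0644 with an estimated correlation. Cholesterol and lipid synthesis genes rose in 12 of 32 cases with none falling (17 and 2 adjusted over the list alone), led by the sterol oxidase gene msmo1 (1.69 ± 0.10) and the lipoprotein receptor gene ldlra (2.09 ± 0.20). Their list had an adjusted p = 0.000529 with an estimated correlation. Of 28 genes of the p53 response 10 rose and none fell (15 and 1 adjusted over the list alone), led by the pro-apoptotic gene bbc3 (1.60 ± 0.18). The p53 list had an adjusted p = 0.00825 with an estimated correlation.

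Cell cycle and replication genes fell in LD eyes with PFNA: 16 of 34 fell and none rose (29 adjusted over the list alone), including the replication helicase gene mcm5 (-1.24 ± 0.15) and the proliferation marker mki67 (-0.67 ± 0.15). The cell cycle list had an adjusted p = 0.00795 with an estimated correlation. Visual cycle genes rose in 11 of 18 cases with none falling (13 adjusted over the list alone; adjusted p = 0.0251 with an estimated correlation). Cone phototransduction genes went both ways, 10 falling and 4 rising of 31 (12 and 8 adjusted over the list alone). The cone list call had an adjusted p = 0.335 with an estimated correlation. The cone channel gene cngb3.2 fell by 0.75 ± 0.09, and the green cone opsin gene opn1mw1 went from 3623 ± 555 to 2003 ± 394 FPKM (SD, n = 4), a change of -0.86 ± 0.18. Among fatty acid oxidation and PPAR target genes 8 of 44 rose and 3 fell (13 and 3 adjusted over the list alone). Camera did not call this list (adjusted p = 0.0636, and 0.196 with an estimated correlation), though it did without eye DD PFNA replicate 4 (0.0438). The kinase gene pdk2a rose by 1.21 ± 0.18, while angptl4 had a change of 0.31 ± 0.20 (adjusted p = 0.385) and cpt1ab one of 0.01 ± 0.27 (adjusted p = 0.995). Without eye DD PFNA replicate 4, which takes part in this test only through the estimate of the spread, 3192 genes passed, 1990 higher and 1202 lower. Among markers of other cell types, camera called endothelial markers as higher (3 of 16 rose and none fell, 6 adjusted over the list alone, 7 without that library; adjusted p = 0.0466 with an estimated correlation). Epidermis and epithelial markers were called as higher too (5 of 28 rose and none fell, 7 and 1 adjusted over the list alone, 8 and 1 without that library; adjusted p = 0.335 with an estimated correlation). Lipoprotein and liver-type plasma genes were called as lower with 0 of 21 passing (adjusted p = 0.669 with an estimated correlation), a call lost without that library (0.0544). The members that passed without it in the other lists were 10 of the light-induced, 13 of the inflammation, 20 rising of the immediate early, 16 of the cholesterol, 14 rising of the p53, 23 of the cell cycle, 11 of the visual cycle, 12 falling and 6 rising of the cone and 13 rising and 3 falling of the fatty acid oxidation genes. Without eye LD DMSO replicate 1, 1304 genes passed.

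In eyes kept under DD, the second comparison gave the largest rise again to fosl1a, from 0.673 ± 0.235 to 30.7 ± 7.21 FPKM (SD, n = 4), a change of 4.22 ± 0.24 (adjusted p = 3.25e-08). The stress transcription factor gene atf3 rose by 3.98 ± 0.18, and the genes of the STAT feedback inhibitors cishb and cish rose by 3.66 ± 0.20 and 3.26 ± 0.15. The largest falls among protein-coding genes were in the fatty acid binding protein gene fabp1b.1 (-2.12 ± 0.50), the photoreceptor calcium sensor gene guca1d (-1.88 ± 0.27) and the chitinase gene chia.2 (-1.73 ± 0.43). The chia.2 call was lost without eye DD DMSO replicate 1 (adjusted p = 0.0601) or replicate 3 (adjusted p = 0.0529). In all, 1983 of 18204 genes passed, 1190 higher and 793 lower with PFNA, 400 of them over 2-fold, and 2549 passed without eye DD PFNA replicate 4.

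Of the 10 light-induced genes 8 rose in DD eyes with PFNA and none fell (9 adjusted over the list alone, and 9 without eye DD PFNA replicate 4), led by cry-dash (1.45 ± 0.12; list adjusted p = 0.00501 with an estimated correlation). Clock repressors and outputs rose in 9 of 18 cases with none falling (13 adjusted over the list alone, 15 without that library), among them the cryptochrome gene cry1b (1.85 ± 0.14). This clock list had an adjusted p = 0.180 with an estimated correlation. Of 32 cholesterol and lipid synthesis genes 16 rose and none fell (20 adjusted over the list alone, 18 without that library), led by msmo1 (1.498 ± 0.098), the desaturase gene scd (1.65 ± 0.20) and the squalene epoxidase gene sqlea (1.45 ± 0.19). The cholesterol list had an adjusted p = 3.76e-05 with an estimated correlation. Glycolysis and hypoxia genes rose in 8 of 35 cases with none falling (9 adjusted over the list alone, 12 without that library), among them pfkfb3 (1.45 ± 0.12) and higd1a (1.93 ± 0.22). The glycolysis list had an adjusted p = 0.00637 with an estimated correlation. Of 21 inflammation genes 9 rose and none fell (11 and 1 adjusted over the list alone, 9 without that library), led by socs3b (2.47 ± 0.19) and stat3 (1.96 ± 0.16). The inflammation list had an adjusted p = 0.0540 with an estimated correlation. Fatty acid oxidation and PPAR target genes rose in 12 of 44 cases and fell in 1 (15 and 1 adjusted over the list alone, 16 and 1 without that library; adjusted p = 0.0563 with an estimated correlation).

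Cone phototransduction genes fell in 13 of 31 cases in DD eyes with PFNA and rose in 3 (15 and 4 adjusted over the list alone, 15 and 4 without eye DD PFNA replicate 4). The cone list had an adjusted p = 0.275 with an estimated correlation. The cone channel gene cngb3.2 fell by 1.55 ± 0.09, the other cone channel gene cnga3b rose by 1.53 ± 0.14, the kinase gene grk1b fell by 1.16 ± 0.11 and opn1mw1 fell by 0.73 ± 0.18. Of 21 neural progenitor genes 5 fell and none rose (7 adjusted over the list alone, 8 without that library; adjusted p = 0.0176 with an estimated correlation). Of 34 cell cycle genes 8 fell and none rose (8 adjusted over the list alone, 9 without that library), mki67 among them (-0.81 ± 0.15). This cell cycle list had an adjusted p = 0.152 with an estimated correlation. Epidermis and epithelial markers rose in 5 of 28 cases with none falling (5 adjusted over the list alone, 6 without that library; adjusted p = 0.275 with an estimated correlation). Exocrine pancreas and gut markers were called as lower, with 2 of 18 falling and 2 rising (5 and 2 adjusted over the list alone, 4 and 1 without that library; adjusted p = 0.631 with an estimated correlation). The deiodinase gene dio2, which makes active thyroid hormone, rose by 2.29 ± 0.22.

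The third comparison asks what constant darkness changed in eyes without PFNA. Digestive enzyme transcripts were among the largest rises in DD: the amylase gene amy2a (chromosome 2, 15612755 to 15626972, plus strand) averaged 19.6 ± 10.1 FPKM in DD and 0.560 ± 1.05 FPKM in LD (SD, n = 4), a change of 3.69 ± 0.56 (adjusted p = 0.000941). The lipocalin gene apoda.2 rose by 3.51 ± 0.56, dap1b by 2.96 ± 0.36 and the prostaglandin D synthase gene ptgdsb.1 by 2.64 ± 0.24. Among protein-coding genes the largest falls were in INHBC (-2.05 ± 0.32), in the orphan nuclear receptor gene esrrgb (-2.01 ± 0.18) and in the heat shock gene hsp70l (-1.96 ± 0.33). In all, 2288 of 18204 genes passed, 1133 higher and 1155 lower in DD.

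Of 34 cell cycle and replication genes 23 fell in DMSO eyes in DD and none rose (26 adjusted over the list alone), including mcm5 (-1.32 ± 0.15) and the topoisomerase gene top2a (-0.86 ± 0.10). The cell cycle list had an adjusted p = 0.00988 with an estimated correlation. Of 26 heat shock and chaperone genes 12 fell and none rose (15 adjusted over the list alone), among them hspa4a (-1.20 ± 0.16) and hspd1 (-0.85 ± 0.13). Their list also had an adjusted p = 0.00988 with an estimated correlation. Cholesterol and lipid synthesis genes fell in 12 of 32 cases and rose in 1 (14 and 2 adjusted over the list alone), led by the squalene synthase gene fdft1 (-1.07 ± 0.17). The cholesterol list had an adjusted p = 0.00198 with an estimated correlation. Visual cycle genes rose in 10 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone), among them rgra (1.18 ± 0.12), the retinoid carrier gene rbp3 (1.32 ± 0.14) and the retinol dehydrogenase gene rdh8a (0.99 ± 0.12). The visual cycle list had an adjusted p = 0.0775 with an estimated correlation. Of 18 exocrine pancreas and gut markers, genes of another organ, 12 rose and none fell (16 adjusted over the list alone; adjusted p = 0.221 with an estimated correlation). Cartilage, bone and connective tissue markers fell in 6 of 29 cases with none rising (6 adjusted over the list alone). Skeletal muscle markers were called as higher with 0 of 29 passing (adjusted p = 0.614 with an estimated correlation for each of these lists).

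The clock gene per1b fell in DMSO eyes in DD by 1.67 ± 0.28 and per3 by 0.48 ± 0.09. The change of per2 was -0.59 ± 0.20 (adjusted p = 0.0696), and it passed without eye DD PFNA replicate 4 (0.0124) or eye LD DMSO replicate 1 (0.0430). The gene clocka had a change of 0.00 ± 0.15 (adjusted p = 0.992) and arntl1a one of 0.13 ± 0.11 (adjusted p = 0.476). Without eye DD PFNA replicate 4, which takes part only through the estimate of the spread, 3996 genes passed. The passing members were 24 falling of the cell cycle, 15 falling and 1 rising of the heat shock, 16 falling and 2 rising of the cholesterol, 11 rising and 1 falling of the visual cycle, 16 rising of the pancreas and gut, 7 falling and 1 rising of the cartilage, bone and connective tissue and 0 of the muscle genes. Without eye DD DMSO replicate 3 the count was 1261, and without eye LD DMSO replicate 2, 3 or 4 it was 1306, 1273 or 1382.

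The fourth comparison asks what constant darkness changed in eyes with PFNA. Among the rises, cpa4 went from 1.12 ± 0.508 FPKM in LD to 16.6 ± 14.9 FPKM in DD (SD, n = 4), a change of 2.76 ± 0.42 (adjusted p = 0.00152), and the cone transducin gene gngt2a rose by 2.55 ± 0.61. Among nuclear protein-coding genes the largest falls were in INHBC (-2.37 ± 0.32), in the activity-induced genes egr1 (-2.09 ± 0.44) and npas4a (-1.94 ± 0.30) and in nfil3-5 (-1.95 ± 0.25). In all, 2928 of 18204 genes passed, 1281 higher and 1647 lower in DD.

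The period genes per2 and per1b fell in PFNA eyes in DD by 1.37 ± 0.20 and 1.17 ± 0.28. Immediate early genes fell in 11 of 28 cases and none rose (14 fell and 3 rose adjusted over the list alone, 9 fell without eye DD PFNA replicate 4; adjusted p = 0.496 with an estimated correlation). Clock activators fell in 5 of 10 cases with none rising (5 adjusted over the list alone, 4 without that library; adjusted p = 0.261 with an estimated correlation), among them the nuclear receptor gene rorcb (-1.27 ± 0.13) and nfil3-5, whose family holds transcriptional repressors. Cone phototransduction genes fell in 10 of 31 cases and rose in 3 (12 and 5 adjusted over the list alone, 12 and 3 without that library; adjusted p = 0.579 with an estimated correlation), including cngb3.2 (-1.09 ± 0.09), cnga3a (-0.89 ± 0.09) and grk1b (-0.74 ± 0.11). Cell cycle genes fell in 14 of 34 cases with none rising (14 adjusted over the list alone, 10 without that library; adjusted p = 0.261 with an estimated correlation), among them top2a (-0.84 ± 0.10) and mki67 (-0.92 ± 0.15). Of 29 cartilage, bone and connective tissue markers 10 fell and none rose (10 adjusted over the list alone; adjusted p = 0.508 with an estimated correlation), and 3 fell without eye DD PFNA replicate 4. Of 18 exocrine pancreas and gut markers 5 rose and none fell (7 and 1 adjusted over the list alone, 5 without that library; adjusted p = 0.000247, and 0.455 with an estimated correlation). Of 21 lipoprotein and liver-type plasma genes 1 rose and none fell (1 adjusted over the list alone, 1 without that library; adjusted p = 0.593 with an estimated correlation). Of 59 nuclear oxidative phosphorylation genes 11 rose and none fell (11 adjusted over the list alone; adjusted p = 0.455 with an estimated correlation), and 7 rose without that library, which had the largest mitochondrial share. The neuropeptide gene vip rose by 1.56 ± 0.17. Without eye DD PFNA replicate 4 the count of all genes was 1980, and without eye LD PFNA replicate 1, 2 or 4 it was 1677, 1462 or 1567.

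The interaction asks whether the PFNA effect in eyes differed between DD and LD. The orphan nuclear receptor gene esrrgb (chromosome 20, 46790056 to 46817223, minus strand) averaged 22.8 ± 2.49 FPKM with PFNA and 2.87 ± 0.678 FPKM with DMSO in DD, against 17.4 ± 5.16 and 14.5 ± 1.69 FPKM in LD (SD, n = 4), a difference of effects of 2.42 ± 0.25 (adjusted p = 0.00113). The repressor gene nfil3-6 averaged 168 ± 41.0 and 171 ± 31.3 FPKM with PFNA and DMSO in DD, against 358 ± 25.4 and 75.9 ± 18.8 FPKM in LD (SD, n = 4), a difference of -2.30 ± 0.28 (adjusted p = 0.00323). The STAT inhibitor genes cishb and cish had differences of 1.80 ± 0.29 and 1.51 ± 0.22, ano2b one of -1.45 ± 0.22 and rorcb one of -1.23 ± 0.18. Of these, nfil3-6, ano2b and rorcb were chosen after their values were seen. In all, 25 of 18204 genes passed, 10 higher and 15 lower, and 60 passed without eye DD PFNA replicate 4. Of these named genes, cishb was lost without eye DD DMSO replicate 1 or 2 (adjusted p = 0.0573 or 0.0525), eye DD PFNA replicate 3 (0.0623), eye LD DMSO replicate 2 or 3 (0.0575 or 0.0533) or eye LD PFNA replicate 1 or 2 (0.0538 or 0.0683). Both ano2b and rorcb were lost without eye LD DMSO replicate 2 (0.0575 and 0.0525) or eye LD PFNA replicate 2 (0.0525 for each). The count of all genes was 9, 12, 13 or 16 without eye DD DMSO replicate 1, 2, 3 or 4, 9 without eye DD PFNA replicate 3, 6, 8 or 15 without eye LD DMSO replicate 2, 3 or 4, and 10 or 6 without eye LD PFNA replicate 1 or 2.

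**Figure D2:**
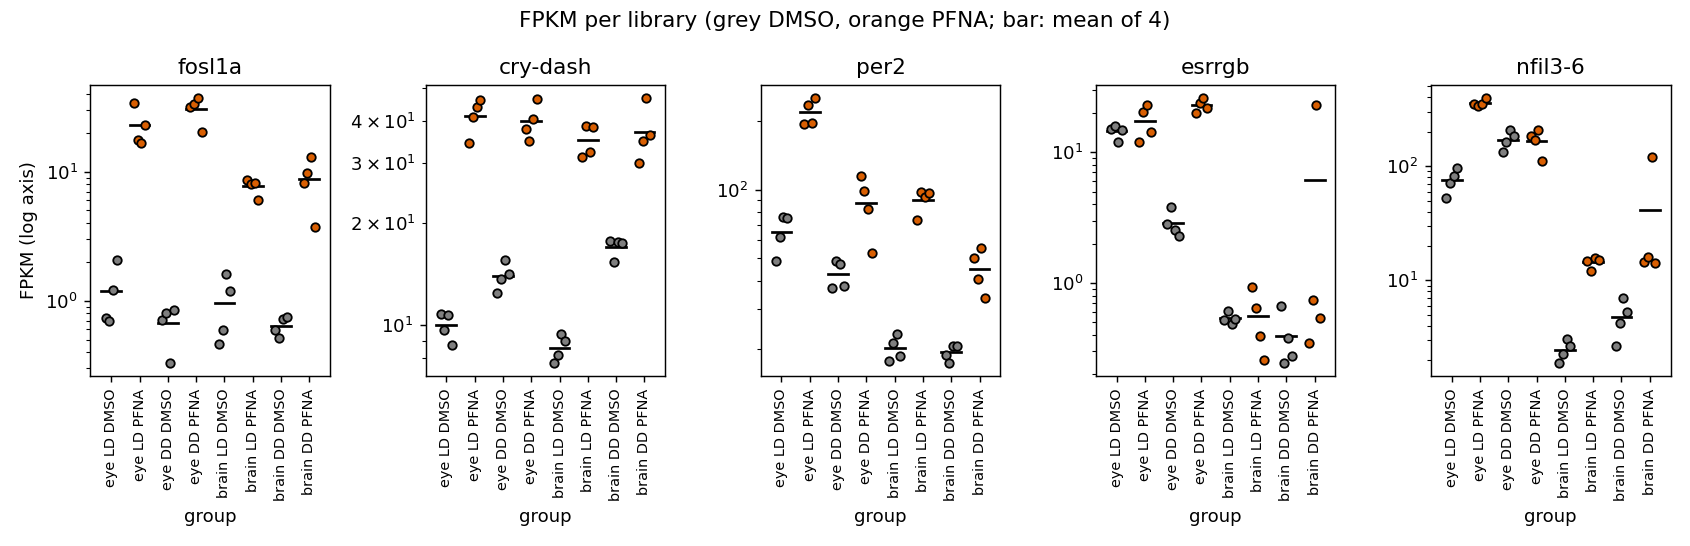
FPKM of fosl1a, cry-dash, per2, esrrgb and nfil3-6 in each library of the 4 eye and 4 brain groups, on a log axis. Points are libraries and bars are means of 4, and cry-dash in LD eyes went from a mean of 9.98 to 41.3 FPKM with PFNA.

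The comparison of brains raised with PFNA or DMSO under LD gave its largest rise among protein-coding genes to the histone gene histh1l (121 ± 46.8 to 894 ± 31.0 FPKM, SD, n = 4; 2.94 ± 0.32, adjusted p = 0.000106), followed by the arrestin-domain gene arrdc3b (2.69 ± 0.26) and the transporter gene slc16a6b (2.27 ± 0.18). The gene fosl1a rose by 2.18 ± 0.27. Of the falls, serpinh1b (-1.76 ± 0.30) and the apelin receptor gene aplnrb (-1.16 ± 0.14) were singled out after their values were seen, as they kept their call when any 1 library of the groups was left out. In all, 405 of 17437 genes passed, 321 higher and 84 lower with PFNA.

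Of 10 light-induced genes 8 rose in LD brains with PFNA and none fell (10 adjusted over the list alone): cry-dash went from 8.57 ± 0.757 to 35.1 ± 3.79 FPKM (1.91 ± 0.13) and per2 from 20.4 ± 2.56 to 90.3 ± 11.1 FPKM (2.095 ± 0.151; SD, n = 4). The list had an adjusted p = 0.00951 with an estimated correlation. Clock repressors and outputs rose in 9 of 18 cases with none falling (15 adjusted over the list alone), led by cry1b (1.53 ± 0.13) and nr1d4b (1.92 ± 0.30). This clock list had an adjusted p = 0.0623 with an estimated correlation. Clock activators rose in 3 of 9 cases with none falling (5 adjusted over the list alone; adjusted p = 0.00951 with an estimated correlation). Cholesterol and lipid synthesis genes rose in 9 of 32 cases with none falling (15 adjusted over the list alone), led by the lipogenic regulator gene srebf1 (1.39 ± 0.12), scd (1.53 ± 0.14) and ldlra (1.48 ± 0.19). The cholesterol list had an adjusted p = 0.00951 with an estimated correlation. Of 29 immediate early genes 5 rose and none fell (12 adjusted over the list alone; adjusted p = 0.0834 with an estimated correlation). The glucocorticoid and thyroid hormone responsive gene klf9 rose by 1.59 ± 0.21. Of 35 cell cycle genes 2 fell and none rose (11 adjusted over the list alone; adjusted p = 0.140 with an estimated correlation). Camera also called markers of other tissues as lower: skeletal muscle markers (1 of 30 fell and none rose, 13 adjusted over the list alone; adjusted p = 2.84e-11, and 0.319 with an estimated correlation) and cartilage, bone and connective tissue markers (1 of 29 fell and none rose, 1 adjusted over the list alone; adjusted p = 1.46e-06, and 0.533 with an estimated correlation). Of 41 fatty acid oxidation and PPAR target genes 5 rose and 1 fell (6 and 5 adjusted over the list alone). Camera did not call the list (adjusted p = 0.827, and 0.967 with an estimated correlation). Without the library labelled brain DD PFNA replicate 3, which takes part only through the estimate of the spread, 1360 genes passed, 967 higher and 393 lower. Passing members were 9 of the light-induced, 16 of the clock repressor, 5 of the clock activator, 15 of the cholesterol, 13 rising and 1 falling of the immediate early, 6 falling of the cell cycle, 2 falling of the muscle, 1 falling of the cartilage, bone and connective tissue and 5 rising and 1 falling of the fatty acid oxidation genes. The count was 205 or 258 without brain LD DMSO replicate 1 or 4, and 215, 229, 222 or 216 without brain LD PFNA replicate 1, 2, 3 or 4.

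In brains kept under DD, the PFNA group holds the library labelled brain DD PFNA replicate 3, and each change is followed by its value without that library. The stress transcription factor gene atf3 rose by 2.97 ± 0.28 (2.67 without it; adjusted p = 4.06e-05 with it) and the heat shock genes hsp70.3 and hsp70.2 by 2.87 ± 0.40 (2.91) and 2.72 ± 0.45 (2.67), with 4 libraries per group. The largest falls were in apoda.2 (-2.80 ± 0.68, -3.35 without it) and the trypsin gene prss1 (-2.64 ± 0.61, -3.27 without it). As an exocrine pancreas marker, prss1 is a gene of another organ. Its DD level with DMSO was lowest in replicate 4 of both tissues (18.68 FPKM in brains, 17.76 FPKM in eyes). Whether its transcripts came from the dissected brain was not tested. In all, 719 of 17437 genes passed, 524 higher and 195 lower with PFNA. Without the library 1145 passed, 832 higher and 313 lower, 655 of them shared with the 719.

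Cholesterol and lipid synthesis genes rose in 13 of 32 cases in DD brains with PFNA and none fell (19 and 1 adjusted over the list alone, 14 and 1 without the library labelled brain DD PFNA replicate 3). Their list had an adjusted p = 0.00599 with an estimated correlation. They were led by scd (2.14 ± 0.14, 2.14 without it), srebf1 (1.31 ± 0.12, 1.26) and the fatty acid synthase gene fasn (1.06 ± 0.12, 0.93). Clock repressors and outputs rose in 9 of 18 cases with none falling (13 adjusted over the list alone, 11 without that library), led by cry1b (1.92 ± 0.13, 1.99) and per3 (0.95 ± 0.11, 0.86). Light-induced genes rose in 6 of 10 (9 adjusted over the list alone, 7 without that library), led by cry-dash (1.06 ± 0.13, 0.95) and per2 (1.15 ± 0.15, 1.04). Each of these 2 lists had an adjusted p = 0.0899 with an estimated correlation. Heat shock and chaperone genes rose in 6 of 25 cases with none falling (12 adjusted over the list alone, 7 without that library; adjusted p = 0.0899 with an estimated correlation), among them hspd1 (1.17 ± 0.12, 1.21). Neural progenitor genes fell in 6 of 24 cases with none rising (8 adjusted over the list alone, 6 without that library; adjusted p = 0.202 with an estimated correlation), led by the Notch target genes her4.2 (-1.60 ± 0.21, -1.42) and her15.1 (-1.18 ± 0.18, -1.12). Exocrine pancreas and gut markers fell in 8 of 16 cases and rose in 1 (14 and 1 adjusted over the list alone, 12 and 1 without that library; adjusted p = 0.271 with an estimated correlation). Camera also called as lower lipoprotein and liver-type plasma genes (1 of 13 fell and none rose, 7 adjusted over the list alone, 1 without that library; adjusted p = 0.444 with an estimated correlation), skeletal muscle markers (0 of 30 passed; 0.558) and cartilage, bone and connective tissue markers (0 of 29 passed; 0.662). The rod opsin gene rho had a change of 1.82 ± 1.55 (adjusted p = 0.545), and -0.48 without that library.

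The call of apoda.2 in DD brains was lost without brain DD DMSO replicate 1, 2 or 3 (adjusted p = 0.0992, 0.0897 or 0.0799) and without brain DD PFNA replicate 1, 2 or 4 (0.0661, 0.0874 or 0.0637). That of prss1 was lost without the same libraries (0.0810, 0.0731 or 0.0624, and 0.0549, 0.0733 or 0.0571). The count of all genes was 397 or 406 without brain DD DMSO replicate 1 or 2 and 454 without brain DD PFNA replicate 2.

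In brains without PFNA, amy2a averaged 22.2 ± 11.6 FPKM in DD and 0.265 ± 0.190 FPKM in LD (SD, n = 4), a change of 3.97 ± 0.57 (adjusted p = 0.00157). The gene dap1b was higher in DD by 3.88 ± 0.45 and apoda.2 by 3.87 ± 0.68. The DD level of the digestive enzyme gene amy2a was lowest in DMSO replicate 4 of both tissues (5.42 FPKM in brains, 4.68 FPKM in eyes). Whether its transcripts came from the dissected tissue itself was not tested. Among nuclear protein-coding genes the largest falls were in the histone gene hist2h3c (-2.20 ± 0.21), in klhl41b (-2.19 ± 0.37), smtlb (-2.17 ± 0.45) and smtla (-2.17 ± 0.37) and in the mitochondrial ATPase gene atad3 (-2.07 ± 0.25). In all, 1085 of 17437 genes passed, 456 higher and 629 lower in DD.

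Cell cycle and replication genes fell in 17 of 35 cases in DMSO brains in DD and none rose (29 adjusted over the list alone), led by mcm3 (-1.08 ± 0.15), the ribonucleotide reductase gene rrm1 (-0.99 ± 0.16) and mcm2 (-1.05 ± 0.17). Their list had an adjusted p = 0.145 with an estimated correlation. Unfolded protein and stress response genes fell in 6 of 38 cases and rose in 1 (10 and 2 adjusted over the list alone), led by the endoplasmic reticulum chaperone gene hspa5 (-1.12 ± 0.13) and hyou1 (-0.76 ± 0.13). The stress response list had an adjusted p = 0.383 with an estimated correlation. Exocrine pancreas and gut markers, genes of another organ, rose in 12 of 16 cases with none falling (15 adjusted over the list alone; adjusted p = 0.383 with an estimated correlation). Immediate early genes fell in 6 of 29 with none rising (10 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Erythrocyte markers fell in 1 of 10 cases with none rising (2 adjusted over the list alone; adjusted p = 0.471 with an estimated correlation). Cartilage, bone and connective tissue markers were called as lower with 0 of 29 passing, and lipoprotein and liver-type plasma genes as higher with 0 of 13 passing and 1 rising adjusted over the list alone (adjusted p = 0.876 with an estimated correlation for each). The latter 2 calls were lost without the library labelled brain DD PFNA replicate 3 (0.0619 and 0.0887). The clock gene per1b fell by 1.43 ± 0.22, cry-dash rose by 0.91 ± 0.13, and per2 had a change of -0.06 ± 0.15 (adjusted p = 0.897). Without the library labelled brain DD PFNA replicate 3, which takes part only through the estimate of the spread, 2763 genes passed. Among the lists the passing members were 23 falling of the cell cycle, 13 falling and 2 rising of the unfolded protein, 14 rising of the pancreas and gut, 9 falling of the immediate early, 2 falling of the erythrocyte, 1 falling of the cartilage, bone and connective tissue and 1 rising of the lipoprotein genes. The count was 677 or 709 without brain DD DMSO replicate 1 or 4, and 581 without brain LD DMSO replicate 1 or replicate 4.

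Constant darkness in brains with PFNA was tested with the library labelled brain DD PFNA replicate 3 in the DD group, and values without it follow each change. The gene dap1b rose by 2.95 ± 0.45 (2.70 without it; adjusted p = 0.00358 with it) and gas7a by 2.43 ± 0.37 (2.82), with 4 libraries per group. Among nuclear protein-coding genes the largest falls were in the activity-induced genes npas4a (-2.62 ± 0.40, -2.14), fosaa (-2.27 ± 0.45, -1.70) and egr4 (-2.27 ± 0.34, -2.15). In all, 1275 of 17437 genes passed, 474 higher and 801 lower in DD, and 1661 passed without that library.

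Immediate early genes fell in 10 of 29 cases in PFNA brains in DD and rose in 2 (15 and 2 adjusted over the list alone, 13 and 3 without the library labelled brain DD PFNA replicate 3; adjusted p = 0.565 with an estimated correlation). Neural progenitor genes fell in 10 of 24 cases with none rising (15 adjusted over the list alone, 12 without that library; adjusted p = 0.413 with an estimated correlation), led by her4.2 (-1.43 ± 0.21, -1.25) and her4.1 (-1.54 ± 0.27, -1.34). Cell cycle genes fell in 12 of 35 cases with none rising (19 adjusted over the list alone, 12 without that library; adjusted p = 0.413 with an estimated correlation), among them top2a (-0.65 ± 0.12, -0.61) and kif11 (-0.69 ± 0.13, -0.66). Erythrocyte markers fell in 2 of 10 cases with none rising (3 adjusted over the list alone, 2 without that library; adjusted p = 0.532 with an estimated correlation). Exocrine pancreas and gut markers rose in 1 of 16 cases with none falling (1 adjusted over the list alone; adjusted p = 0.755 with an estimated correlation), and that call was lost without that library (0.309). The chaperone gene hspa5 changed by -1.17 ± 0.13 (-1.06 without that library), per2 by -1.003 ± 0.151 (-1.11) and per1b by -1.19 ± 0.22 (-1.06). The count of all genes was 607, 496, 618 or 597 without brain LD PFNA replicate 1, 2, 3 or 4.

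**Figure D3:**
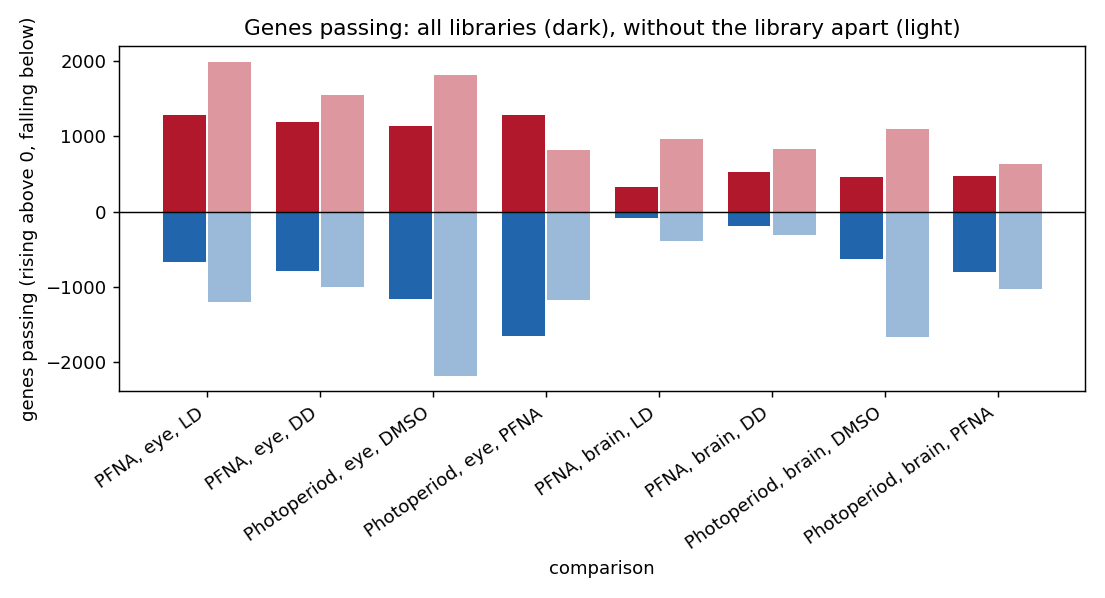
Number of genes passing the test in each of the 8 PFNA and photoperiod comparisons, rising (above 0) and falling (below 0), with all libraries and without the library of the tissue that stood apart. In LD eyes 1956 genes passed for PFNA with all libraries and 3192 without eye DD PFNA replicate 4.

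In brains the PFNA effect was not shown to differ between DD and LD for any gene. For per2 the difference of effects was -0.95 ± 0.21 (adjusted p = 0.440), for per3 it was 0.75 ± 0.15 (adjusted p = 0.326) and for nr1d2a it was -0.91 ± 0.23 (adjusted p = 0.492), with 4 libraries per group. By limma 0 of 17437 genes passed, with 961 at an unadjusted p under 0.05, and limma with voom weights also gave 0. With weights for single libraries 22 passed, and 1 passed without the library labelled brain DD PFNA replicate 3 and without brain DD PFNA replicate 1 or 4.

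**Figure D4:**
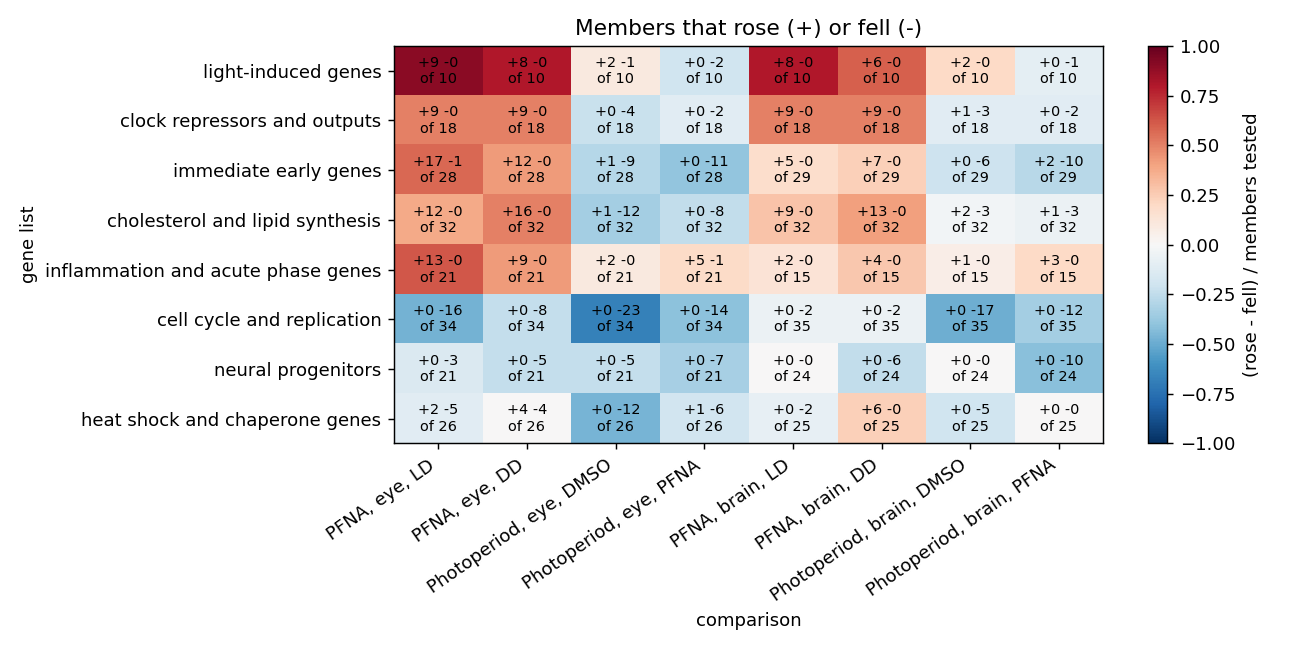
Members of 8 gene lists that rose minus those that fell, as a share of the tested members, in the 8 PFNA and photoperiod comparisons, with the numbers of members printed. In DD eyes with PFNA, 16 of 32 cholesterol and lipid synthesis genes rose and none fell.

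The last comparisons ask whether the PFNA effect differed between eye and brain. Under LD 0 of 16441 genes passed by limma, with 908 at an unadjusted p under 0.05 and 1 gene with voom weights. Under LD the count was 3 without eye LD PFNA replicate 3, 1 without brain LD DMSO replicate 1, 7 without eye DD PFNA replicate 4 and 22 without the library labelled brain DD PFNA replicate 3. Under DD the phosphatase gene ptpn20 (chromosome 13, 31177934 to 31228552, plus strand) averaged 15.8 ± 2.67 FPKM with PFNA and 29.7 ± 4.22 FPKM with DMSO in eyes, against 7.91 ± 3.26 and 3.93 ± 0.749 FPKM in brains (SD, n = 4), a difference of -1.68 ± 0.24 (adjusted p = 0.00169). The AP-1 gene jun had a difference of 1.76 ± 0.34 (adjusted p = 0.0408) and the neuropeptide gene cort one of 1.62 ± 0.29 (adjusted p = 0.0396). The jun call was lost without any single library of the DD groups other than eye DD PFNA replicate 4 and the library labelled brain DD PFNA replicate 3 (adjusted p between 0.0575 and 0.0948). The cort call was lost without eye DD DMSO replicate 1, 3 or 4 (0.0719, 0.0524 or 0.0890), eye DD PFNA replicate 1 (0.0603), brain DD DMSO replicate 1 or 2 (0.0859 or 0.0948) or brain DD PFNA replicate 2 (0.0587). Under DD 10 of 16441 genes passed, 4 with the higher effect in eyes and 6 with the higher effect in brains. With the replicate number as a block, set within each tissue apart, 2 passed, ptpn20 and cort, so the jun call was lost. This block ties no eye library to a brain library, so a pairing of eye and brain samples was not modelled. The count was 137 without the library labelled brain DD PFNA replicate 3, where the differences were -1.45 for ptpn20 (adjusted p = 8.2e-05), 2.02 for jun (0.000996) and 1.58 for cort (0.00945). It was 1, 2, 2 or 1 without eye DD DMSO replicate 1, 2, 3 or 4, 4 without eye DD PFNA replicate 1, 1, 1 or 6 without brain DD DMSO replicate 1, 2 or 4 and 3 without brain DD PFNA replicate 2.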

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

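The tests of the 3 patterns weighed here were chosen after the result was seen, while the splits of the libraries were planned. Regrouping the libraries of a contrast tells how often another split gives as many genes as the real one. Of the 35 splits of 8 libraries, 1 (the real split) gave as many genes as the real one in each of the 8 PFNA and photoperiod contrasts. This is the smallest share that 35 splits can give, each contrast taken alone. The other splits mix the compared groups, so a real difference adds to their spread and lowers their counts. The splits cannot tell treatment or photoperiod from anything else that the 4 libraries of a group share. The real count and the highest count of the other splits were 1956 and 1 for PFNA in LD eyes, 1983 and 31 in DD eyes, 405 and 1 in LD brains and 719 and 58 in DD brains. For photoperiod they were 2288 and 1 in DMSO eyes, 2928 and 4 in PFNA eyes, 1085 and 2 in DMSO brains and 1275 and 4 in PFNA brains. For the interactions and tissue differences, residuals of the fit without the tested difference were instead permuted among the libraries of a tissue. Of 100 such draws, the real result included, 1 gave as many genes as the interaction in eyes (25, at most 1 otherwise). Likewise 1 gave as many as the tissue difference under DD (10, at most 6 otherwise). For the interaction in brains and the tissue difference under LD the real count was 0, which every draw reaches, so the draws cannot test it. The highest other draw gave 13 genes for the interaction in brains and 1 for the tissue difference under LD. The draw with 13 genes points to a structure among the brain libraries, which include the library labelled DD PFNA replicate 3, and what it follows was not tested. For the gene list calls 7 of 100 splits gave at least the real 152, the highest other gave 168 and the median of the others was 122. Chance was therefore not excluded for their number, and camera at the preset correlation called many lists under arbitrary groupings too. These splits dealt all 16 libraries of a tissue at random into its 4 groups. Such a deal can hold part of a real effect, or a library that stood apart, so its calls are not a pure chance level. The same holds for the counts per list that follow. Of the 152 called pairs, 45 were reached by fewer than 5 of 100 splits. Of the called lists described for PFNA, 5 or more splits, the real one included, gave as small a p to cone phototransduction (7), cholesterol (11), epidermis (23) and liver-type plasma genes (59) in LD eyes, to clock repressors (5), cone phototransduction (5), cell cycle (31), epidermis (20) and pancreas and gut (45) in DD eyes, to cell cycle (10), muscle (17) and cartilage (31) in LD brains and to pancreas and gut (13), liver-type plasma genes (30), muscle (30) and cartilage (47) in DD brains. For photoperiod these were cholesterol (13), pancreas and gut (5), muscle (36) and cartilage (50) in DMSO eyes and immediate early genes (23), erythrocyte markers (20), liver-type plasma genes (40) and cartilage (64) in DMSO brains. In PFNA eyes they were immediate early genes (34), clock activators (7), cone phototransduction (23), cell cycle (30), cartilage (22), pancreas and gut (17), liver-type plasma genes (45) and oxidative phosphorylation (16), and in PFNA brains immediate early genes (20), cell cycle (5), erythrocyte markers (16) and pancreas and gut (54).

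The library labelled brain DD PFNA replicate 3 carries eye transcripts, with a position of 0.972 between brain and eye where its group's other libraries lie at 0.01 to 0.031. An exchange with an eye library of the series is argued against by 0 eye libraries lying nearer the brain end, and a brain sample mixed with eye tissue by a brain share of 1.54% from brain-enriched genes, below the highest eye library (6.45%) and far below the lowest other brain library (76.7%). PFNA exposure in darkness as the cause is argued against by 0 of the other 3 libraries of the group lying above the highest brain library of the other groups. An eye library under a brain label stays a candidate explanation, since 0.972 lies within the 0.948 to 1.02 of the 12 eye libraries outside the groups that set the scale, and its values correlated across genes most with eye DD PFNA replicate 3 (r = 0.95), and with replicate 2 at r = 0.945, against at most 0.665 with another brain library.

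Genes within 1000 kb of a chromosome end were lower in DD than other genes: the gap of the median log2 changes was -0.253 and -0.238 in DMSO and PFNA eyes and -0.225 and -0.225 in DMSO and PFNA brains (-0.131 in PFNA eyes without eye DD PFNA replicate 4, -0.188 in PFNA brains without the library labelled brain DD PFNA replicate 3), where 1000 rotations of the positions within chromosomes stayed between -0.0884 and 0.0713. The libraries that stood apart are argued against as the whole cause by -0.225, the gap nearest 0 in the DMSO contrasts, which hold neither, and gene length by -0.229, the gap nearest 0 within length classes. In brains a length bias of the libraries is argued against, since the gap of the library scores was 0.213 and stayed 0.209 with the libraries' length trend in the model (permutation p = 2e-05, 15 libraries). In eyes the gap of the library scores went from 0.264 to 0.0442 ± 0.0489 (standard error) with the length trend in the model (permutation p = 0.382, 16 libraries). The library scores and the length trend moved together within the eye groups (r = 0.949), so this model cannot separate them. Within length classes the eye gaps were -0.276 with DMSO and -0.286 with PFNA, which argues against a bias acting through gene length. What the length trend of the eye libraries follows was not tested. The photoperiod itself stays open in both tissues, and GC content was not tested, as no sequence was used here.

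Light-induced genes rose with PFNA in eyes and brains under LD and DD, though in DD brains 6 of 10 passed and the list call was lost with an estimated correlation (adjusted p = 0.0899). The libraries that stood apart are argued against, since 16 of the light-induced gene calls in DD eyes and brains were made without them against 14 with them. Under LD the medians of the core clock activators were 0.397 in eyes and 0.343 in brains, above 0 beside risen repressors. The 5 activators in eyes ran from -0.0887 to 1.24. This argues against a shift of clock phase that lowers activators where repressors rise. Other shifts stay open, as the time of collection is not stated. Under DD the activator medians were -0.029 in brains and 0.0465 in eyes, over 4 and 5 genes that went both ways, and 0.104 and 0.131 without the libraries that stood apart. A shift of clock phase and an effect of PFNA on these genes cannot be told apart there either. Light reaching the PFNA groups kept in darkness also stays open: genes that fell in darkness in the other tissue had a median PFNA effect under DD of 0.0321 in eyes and 0.0324 in brains, but 0.129 and 0.0747 without these libraries, against falls of 0.62 and 0.425. The light-induced list itself was not shown to be lower in darkness without PFNA. Camera did not call it between DD and LD with DMSO (adjusted p = 0.697 in eyes and 0.0908 in brains). An effect of PFNA may account for the rise under LD, as a hypothesis found and tested on these data.

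Effects that differed between groups by a test of the difference were 25 genes for the interaction of PFNA and photoperiod in eyes and 10 genes for the eye and brain difference under DD. The named ones were esrrgb (2.42), nfil3-6 (-2.30), cishb (1.80), cish (1.51), ano2b (-1.45) and rorcb (-1.23) for the interaction and ptpn20 (-1.68), jun (1.76) and cort (1.62) for the tissue difference, all as differences of log2 changes. The jun call was lost with the replicate number as a block within each tissue, which ties no eye library to a brain library.

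Of 294 groups of 4 libraries tested for the named genes, 23 held a library far from the other 3 on the log2(FPKM + 1) scale, where chance marks about 1 in 20 groups, or 15 of 294. In LD eyes with PFNA these were il11a (16.1 FPKM) and cebpb (53.6) in replicate 1, mki67 (16.5) in replicate 2, serpinh1b (0.976) in replicate 3 and cngb3.2 (20.9) in replicate 4. In LD eyes with DMSO they were angptl4 (32.1) and rbp3 (151.8) in replicate 1 and opn1mw1 (4448) and amy2a (2.14) in replicate 2. In DD eyes they were cngb3.2 (30.96) in DMSO replicate 1, amy2a (4.68) in DMSO replicate 4 and egr1 (1.92) in PFNA replicate 4. In DD brains with DMSO they were smtla (0.694) in replicate 1, cry-dash (15.3) and hspa5 (36.5) in replicate 2, and apoda.2 (3.54), prss1 (18.7) and amy2a (5.42) in replicate 4. In DD brains with PFNA they were kif11 (5.68) in replicate 1, srebf1 (40.8) in replicate 2, and per3 (58.4) and gas7a (3.46) in the library labelled replicate 3. In LD brains it was smtla (1.79) in DMSO replicate 1. Of 40 groups tested on library measures 4 held a library far from the others: the fragment totals of eye DD DMSO replicate 4 (9.39 M fragments) and eye LD DMSO replicate 2 (15.7 M), and the brain to eye position (0.972) and the chromosome-end score (-0.298) of the library labelled brain DD PFNA replicate 3.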

How the results depend on the processing

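The fits with voom weights, those leaving out a library that takes no part in the contrast, those leaving out a library for the gene lists and that leaving out both libraries that stood apart were chosen after seeing the data, and the other alternatives were planned. Of 305 named values that passed, 255 kept their call under pseudocount 0.1, median-ratio scaling, quantile normalization, a replicate block and leaving out each library, and 50 lost it under at least 1 of these. Of 167 that did not pass, 17 did so under at least 1, and no named value that passed turned its direction under them. The remaining settings were run for the counts and not for single genes. With limma's array weights the counts were 3794 for PFNA in LD eyes, 4598 for photoperiod in DMSO eyes, 90 for the interaction in eyes, 2135 and 1175 for PFNA in LD and DD brains, 2721 and 3469 for photoperiod in DMSO and PFNA brains, 22 for the interaction in brains, and 167 and 109 for the tissue differences under LD and DD. With only the compared groups in the fit, which leaves fewer libraries for the spread, they were 3108 and 734 for PFNA in LD and DD eyes, 3546 and 348 for photoperiod in DMSO and PFNA eyes, 1210 and 59 for PFNA in LD and DD brains and 312 for photoperiod in PFNA brains. The tissue difference under LD gave 10 genes with no filter, 2 with median-ratio scaling and 1 with voom. That under DD gave 2 with no filter, 17 with median-ratio scaling, 30 with quantile normalization and 2 (ptpn20 and cort) with a replicate block. Gene list calls fell from 152 to 20 with an estimated correlation. The cause of these shifts was not tested.

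Leaving out 1 library gave 1304 to 3192 and 1332 to 2549 genes for PFNA in LD and DD eyes, 1261 to 3996 and 1462 to 3558 for photoperiod in DMSO and PFNA eyes, 6 to 60 for the interaction in eyes, 205 to 1360 and 397 to 1145 for PFNA in LD and DD brains, 581 to 2763 and 496 to 1661 for photoperiod in DMSO and PFNA brains and 0 to 1 for the interaction in brains. It gave 0 to 22 for the tissue difference under LD and 1 to 137 under DD, where leaving out both libraries that stood apart gave 140. Replicate numbers did not pair the libraries within a tissue, where 2 of 24 same-number pairs in eyes and 6 of 24 in brains had a residual correlation over 0.1. Between eye and brain 14 of 16 libraries matched best with their own number, a hint of shared samples. No fit here took such a pairing into account, as the replicate block was set within each tissue. The spread between replicates limits small changes, as the simulated 2-fold changes were called for 44 of 100 genes in DD brains. That simulated spread included the library labelled brain DD PFNA replicate 3, and recovery without it was not simulated. Without it 1360 genes passed for PFNA in LD brains, against 405 with it, though it enters that contrast only through the spread.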

Other observations

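The counts without the libraries that stood apart and the genes singled out in this part were chosen after the data were seen. PFNA moved 135 genes the same way in all of its contrasts (LD and DD eyes, LD and DD brains), 121 up and 14 down, while without the libraries that stood apart 311 passed in all of them, 272 up and 38 down in each. Among genes with a given name, those with the largest mean rise without these libraries were the AP-1 gene fosl1a (3.07), the stress gene atf3 (2.68), cebpb (2.43), il11a and the polyamine synthesis gene odc1 (2.32). The set also held cry1b (1.83), ldlra (1.64), scd (1.58), cry2 (1.56) and cry-dash (1.55). The largest mean falls among genes with a given name were in ccnf (-0.90), cdca7a (-0.88), mrs2 (-0.85), zmynd8 (-0.82) and sephs1 (-0.81).

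Constant darkness moved 154 genes the same way in eyes and brains with DMSO and with PFNA, 56 up and 98 down, while without the libraries that stood apart 303 passed in all of these contrasts, 88 up and 214 down in each. Down in the latter set were npas4a (-1.53), egr4 (-1.51), per1b (-1.25), hspa5 (-1.09) and the sterol regulator srebf2 (-1.08), and up were dap1b (2.96), ptgdsb.2 (1.52), the serpin serpini1 (1.33), the lysosomal protease ctsba and lpin1 (1.16).

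The PFNA effects under LD and DD shared 621 rising and 211 falling genes in eyes, where chance would give 83.9 and 29.3, with 5 genes in opposite directions. Without eye DD PFNA replicate 4 they shared 984 and 397 (170 and 65.8 by chance), with 12 in opposite directions. In brains they shared 180 and 32, where chance would give 9.65 and 0.939, with 0 in opposite directions by limma, and 464 and 90 without the library labelled brain DD PFNA replicate 3 (46.1 and 7.05 by chance). Between eyes and brains PFNA shared 238 rising and 46 falling genes under LD (22.9 and 3.13 by chance) and 308 and 68 under DD (35.1 and 7.37 by chance). Across genes the log2 changes correlated with r = 0.522 and 0.493, genes not being independent replicates. The contrasts of each pair share no library, but this does not make them independent. Those of 1 tissue share the estimate of the spread. Between eye and brain 14 of 16 libraries matched best with their own replicate number. The chance counts take neither into account. Without the libraries that stood apart the counts shared between eyes and brains were 602 and 192 under LD and 453 and 108 under DD.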
